A study of Mus musculus with 4 samples.

How the data were processed

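RNA bound to NONO was profiled by RNA immunoprecipitation and sequencing (RIP-seq) in mouse primary hepatocytes, cells freshly taken from liver and kept in culture, with or without added proline. NONO is an RNA-binding protein of paraspeckles, nuclear bodies that hold back certain RNAs, and per the series' design text it served as a stand-in for them. Per the labels' protocols, cells were lysed in polysome lysis buffer, part of the cleared lysate was kept as input, the rest was incubated with antibody on magnetic Dynabeads, DNase I and proteinase K removed DNA and protein, and RNA was recovered with Trizol. Libraries were made with the NEBNext Ultra RNA kit, per the labels' protocols. The 4 libraries fall into 4 groups of 1 library: control input, control NONO IP, proline input and proline NONO IP. The proline dose and the time of treatment are not given in the sources used here, and no mock IP was analysed here.

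The authors deposited 1 table per library with FPKM (fragments per kilobase of transcript, scaled to the total reads of the library) for 21163 mouse Ensembl transcripts, in the same order in every table. The submitters' processing notes name the genome builds GRCm38 and mm10, which are the same mouse assembly. The aligner, the counting tool, the annotation release and the choice of the listed transcripts are not given in the sources used here. The tables hold transcript identifiers without gene names, and the gene table at hand pairs 0 of its genes with an Ensembl identifier, so 0 of the 21163 transcripts could be named. The 32 gene lists fixed in advance (paraspeckle proteins, gluconeogenesis, proline metabolism, markers of other liver cells and others) could therefore not be measured, and neither could the restriction to protein-coding genes. Transcripts could not be summed per gene or sorted by biotype either, so every count below is a count of transcripts, mitochondrial, small RNA and pseudogene transcripts included.

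FPKM values carry no depth of their own, but the deposited values proved to be whole multiples of a step set by transcript length and library total. For each library the total was found as the number for which the lowest values, each taken as 1 read, give whole transcript lengths. It came out within 0.0002 of a whole number in each of the 4 libraries. The smallest whole length and whole read numbers that give a transcript's values in all libraries, to the last deposited digit, were then taken. They were found for 20229 of the 20230 transcripts with a value above 0. Because the smallest solution was taken, a transcript's reads can be too few where its true length and reads share a factor. The procedure was tested on simulated data with known answers: 4 of 4 totals were recovered exactly, as were reads and length for 94.6% of 19727 detected transcripts and for 96.3% of the 12365 with a mean FPKM of at least 1. Whether the counted unit is a single read or a fragment (a read pair) is not given in the sources used here; it is called a read throughout, and if the 2 reads of a pair were counted apart, the counting intervals would be too narrow. The recovered reads served for depth, for counting intervals and for thinning; no count model was fitted.

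Differences were taken on log2(FPKM + 1), with the pseudocount of 1 making changes of low transcripts smaller than their FPKM ratios. They were computed for transcripts with a mean FPKM of at least 1 over the 4 libraries, with FPKM as deposited, and a transcript was counted as higher or lower at a difference of at least 1 (2-fold). The 5 comparisons were NONO IP over input in control, the same in proline, proline over control in the inputs, proline over control in the IPs, and the change in NONO enrichment, which is the second difference minus the first. There are no replicates, so no test was run and no p-value is given: each comparison sets libraries side by side, not conditions. Intervals are 95% intervals of the FPKM ratio from the reads, exact (Clopper-Pearson) for 2 libraries and a normal approximation on the log ratio, with 0.5 added to each read number, for the change in enrichment. They cover counting error only, and PCR copies and variation between cultures lie outside them. A transcript is called beyond counting error where its interval excludes a ratio of 1.

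The same comparison steps were tested on simulated libraries close to the real depth. Their totals were set slightly off the real ones, with the control IP somewhat deeper and the proline IP somewhat shallower. Of 12169 unchanged transcripts, 211 were called higher and 255 lower for proline IP over control IP, 103 of them beyond counting error. For the change in enrichment, 244 of 12169 were called higher and 265 lower, 116 of them beyond counting error. Of 100 transcripts raised 4-fold in the proline IP, 99.0% were called, and of 100 lowered 4-fold, 77.0%; for the change in enrichment the shares were 99.0% and 80.0%.

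The rule for named transcripts, fixed before the data were examined, takes for each comparison the 10 largest rises and 10 largest falls among transcripts with a mean FPKM of at least 5 and a value above 0 in every library compared. Its exclusion of mitochondrial, small RNA, pseudogene and unnamed genes could not be applied. Since no names can be given, only the first 2 in each direction are described, besides transcripts chosen for their IP reads after the values were seen. Identifiers are given only for the first 2 in each direction of control IP over control input, wherever these transcripts recur. Alternatives set before the data were examined were pseudocounts of 0.1 and 5, no FPKM filter, a mean FPKM of at least 5, scaling of each library to the same FPKM total, and centring of the log2 differences on their median over transcripts with a mean FPKM of at least 5. Setting transcripts not listed in a table to 0 changes nothing, because all tables list the same ones. Further alternatives were chosen after the data had been seen and are described with their values. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.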

Results

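RIP-seq libraries of mouse primary hepatocytes were compared to ask whether proline alters which mRNAs are held with the paraspeckle protein NONO. The input libraries, which sample the whole lysate, held 22188003 reads in control and 20826758 in proline, where a read is the unit counted in the tables, a single read or a fragment. The IP libraries were far smaller, at 1786928 reads in control and 954824 in proline, 12.4 and 23.2 times fewer than in the control input. A transcript of 3000 nt at 1 FPKM thus corresponds to 66.6 reads in the control input, 62.5 in the proline input, 5.36 in the control IP and 2.86 in the proline IP. A value of 0 allows a share of up to 1.35e-05% of the control input reads and up to 0.000314% of the proline IP reads (3 reads of the total). The listed transcripts took 97.8% of the reads in the control input, 94.1% in the control IP, 97.9% in the proline input and 95.6% in the proline IP. These shares count recovered reads. In the simulated data, with all reads on listed transcripts, 98.2% of them were recovered, so part of the shortfall can come from the recovery. Values above 0 were found for 16048 transcripts in the control input, 19081 in the control IP, 16041 in the proline input and 16875 in the proline IP. At least 10 reads were found for 13341, 11227, 13361 and 8810 of them, in the same order. The comparisons below use the 12168 transcripts with a mean FPKM of at least 1.

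In untreated hepatocytes 1 transcript dominated the NONO IP. ENSMUST00000038863, 3894 nt long, stood at 30.2 FPKM in the control input and 21030 FPKM in the control IP, a ratio of 697 (95% counting interval 670 to 725), and took 8.19% of all control IP reads. The next by size of rise was ENSMUST00000179797, of 449 nt, at 3.51 FPKM in the input and 1253.8 FPKM in the IP, a ratio of 357 (255 to 515). A transcript of 21388 nt, chosen after its values were seen because it held the second most control IP reads, was 24.8 times higher in the IP (24.4 to 25.2). Among the falls that come first under the naming rule, which ranks on the log2(FPKM + 1) scale, ENSMUST00000059888 went from 32.3 FPKM in the input to 1.048 FPKM in the IP, a ratio of 0.0324 (0.0148 to 0.0616) on 9 IP reads. ENSMUST00000029574 went from 27.3 to 0.807 FPKM, a ratio of 0.0295 (0.00957 to 0.0689) on 5 IP reads. These identifiers are not paired with gene names in the deposited data, and all other transcripts are told apart by their recovered length.

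Over the 12168 transcripts, 1633 (13.4%) were at least 2-fold higher in the control IP than in the control input and 1771 (14.6%) at least 2-fold lower. Of these, 1600 and 1720 were beyond counting error. A mean input below 1 FPKM was found for 636 of the 1633 higher ones and 1 of the 1771 lower ones. The filter admits such transcripts only through their IP level. The median log2 difference was -0.14, and the quartiles of the transcripts were -0.71 and 0.50. The split into higher and lower depends on the scaling: 48.0% of the called transcripts were higher with FPKM as deposited, 61.5% with each library scaled to the same FPKM total, and 72.3% with the differences centred on their median.

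The log2 difference of IP over input fell steadily with abundance in the lysate. The classes of input level take all listed transcripts, because the filter on mean FPKM admits low-input ones only through high IP values: 888 of the 9750 transcripts with a mean input below 1 FPKM pass it. The median log2 difference between control IP and control input was 0.60 for those 9750 transcripts, of which 2510 were at least 2-fold higher in the IP. They include 6996 transcripts below 0.1 FPKM in the inputs, whose control IP median was 0.554 FPKM. An IP floor of that level gives a positive difference by itself, so the median of this class need not show enrichment. For the next classes the median was lower. The median difference was 0.23 for the 2918 transcripts at 1 to 5 FPKM, -0.18 for the 4847 at 5 to 20 FPKM, -0.57 for the 3043 at 20 to 100 FPKM and -0.84 for the 605 at 100 FPKM or more. In the most abundant class 30 transcripts were at least 2-fold higher in the IP and 248 at least 2-fold lower. Among the filtered transcripts, length made a smaller difference: the median was -0.25 for the 1060 transcripts under 1000 nt and -0.0046 for the 519 of 8000 nt or more. The input level behind these classes is also the denominator of the compared ratio.

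**Figure D1:**
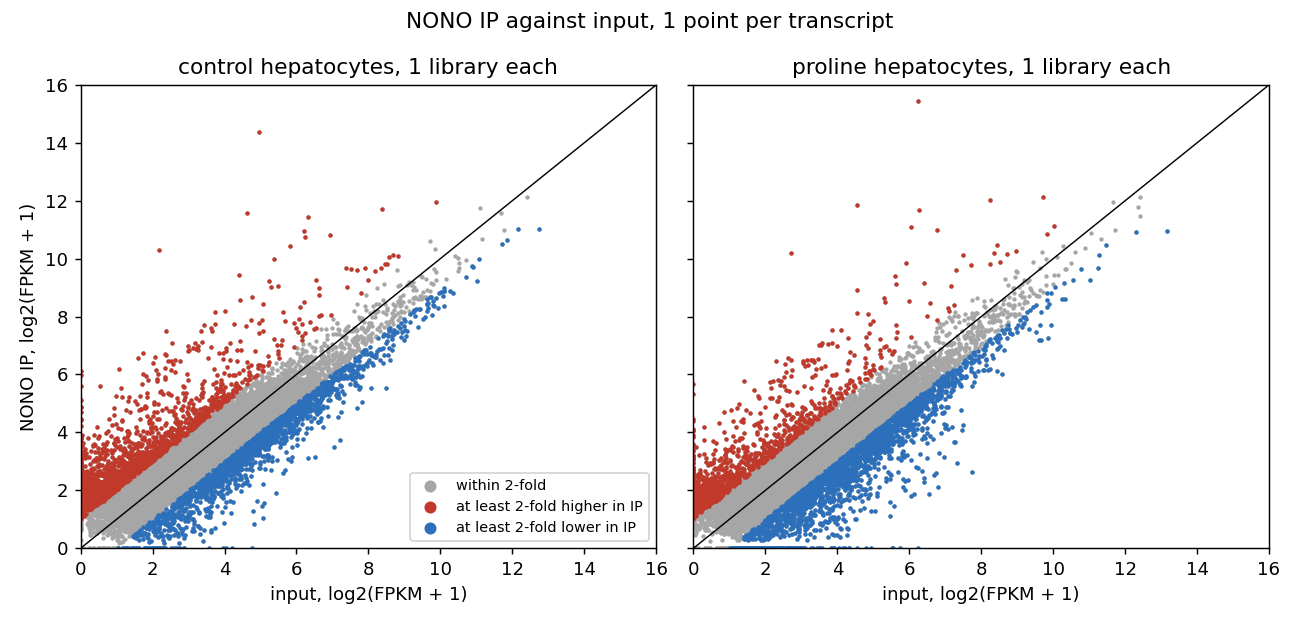
NONO IP against input in control (left) and proline (right) hepatocytes, on log2(FPKM + 1) axes, with 1 point per transcript for 12168 transcripts and 1 library per axis. Red and blue points are at least 2-fold higher or lower in the IP; red points gather at low input, where the filter admits transcripts only through their IP level, and the top point in each panel is the transcript with 8.19% of control and 17.4% of proline IP reads.

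**Figure D2:**
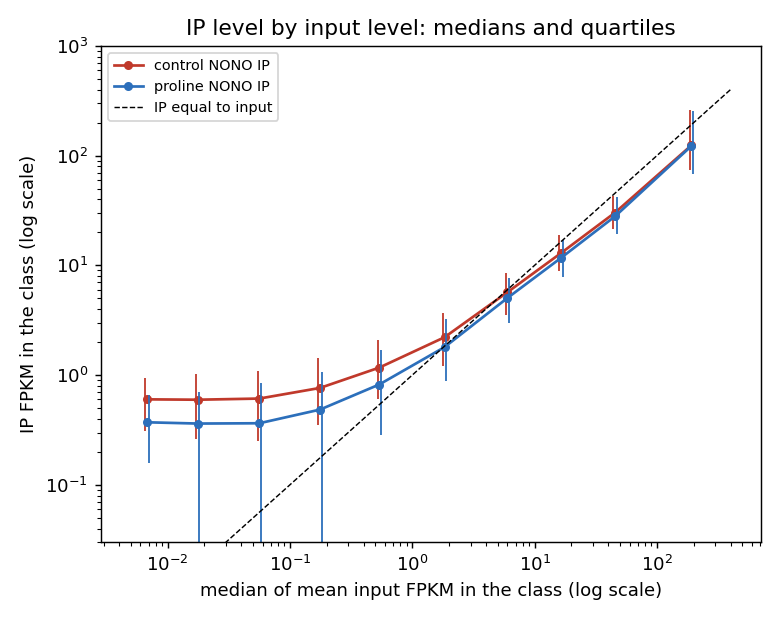
Median FPKM in the NONO IPs (points, with lines from the lower to the upper quartile of transcripts) by class of mean input FPKM, on log axes, 1 library per group; a quartile of 0 runs to the lower edge. Above 0 and below 0.1 FPKM in the inputs the IP medians stay level, near 0.612 FPKM in control and 0.364 FPKM in proline, and at high input both lie below the dashed line of equal level.

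In proline-treated hepatocytes the same pair of transcripts came first under the naming rule. ENSMUST00000038863 stood at 74.4 FPKM in the proline input and 44577 FPKM in the proline IP, a ratio of 599 (584 to 615), and took 17.4% of all proline IP reads. ENSMUST00000179797 stood at 5.56 and 1164 FPKM, a ratio of 209 (157 to 284). The 21388-nt transcript was 14.1 times higher in the IP (13.8 to 14.4). The first falls under the naming rule, ranked on the log2(FPKM + 1) scale, rested on 1 IP read each: a transcript of 201 nt went from 215 FPKM in the input to 5.21 FPKM in the IP (ratio 0.0242, 0.000612 to 0.135), and one of 312 nt from 111 to 3.36 FPKM (ratio 0.0303, 0.000767 to 0.170).

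In proline 1080 transcripts (8.88%) were at least 2-fold higher in the IP than in the input and 2373 (19.5%) at least 2-fold lower, 985 and 2193 of them beyond counting error. A mean input below 1 FPKM, where the filter admits transcripts only through their IP level, was found for 547 and 6 of them. The median log2 difference was -0.31. By mean input level, again over all listed transcripts, the median went from 0.28 below 1 FPKM to -0.11 at 1 to 5 FPKM, -0.33 at 5 to 20 FPKM, -0.61 at 20 to 100 FPKM and -0.74 at 100 FPKM or more. The lowest class again holds the 6996 transcripts below 0.1 FPKM in the inputs, whose proline IP median was 0.233 FPKM. The share of higher among called transcripts was 31.3% with FPKM as deposited, 41.1% with equal FPKM totals and 62.1% with centred differences.

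The enriched transcripts of control and proline overlapped. Of the 1633 enriched in control and the 1080 enriched in proline, 765 were shared, where lists independent within the 5 classes of input level would share 457. Of the depleted ones 1031 were shared, where such lists would share 438. Part of the first overlap comes with the filter, which selects low-input transcripts on their IP level. Among the 10404 transcripts with a mean input of at least 2 FPKM, a limit chosen after seeing the data at which the filter removes none, 274 of the 807 enriched in control and the 418 enriched in proline were shared, against 42.1 for lists independent within input classes. Among all 12168 transcripts, 568 of the 868 enriched in control alone lay above 0 in proline as well. Of the 740 depleted in control alone, 659 lay below 0 in proline, where the median over all 12168 was -0.31. The filter bears on the first of these counts too. Opposite calls were few: 48 transcripts were higher in the control IP and lower in the proline IP, each against its own input, and 5 were the other way round, where lists independent within input classes would give 185 and 61.7. Over all 12168 transcripts the enrichment in control and in proline had a Pearson correlation of 0.70 and a Spearman correlation of 0.65. These correlations are across transcripts, which are not independent replicates.

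Between the inputs, which report whole-lysate RNA, more transcripts were higher in proline than lower. A transcript of 1664 nt rose from 1.22 FPKM in control to 59.5 FPKM in proline, a ratio of 48.8 (36.3 to 67.1), and one of 741 nt from 2.37 to 77.8 FPKM, a ratio of 32.8 (23.9 to 46.4). A transcript of 1215 nt fell from 89.99 to 1.62 FPKM, a ratio of 0.0180 (0.0129 to 0.0245), and one of 5904 nt from 18.7 to 1.0003 FPKM, a ratio of 0.0534 (0.0442 to 0.0641). In all 1104 transcripts (9.07%) were at least 2-fold higher in proline and 388 (3.19%) at least 2-fold lower, with 1103 and 388 beyond counting error. The median log2 difference was -0.01. With 1 library on each side, the difference between these cultures cannot be set against the spread between cultures of one kind.

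Between the IPs more transcripts were lower in proline than higher. The most-read transcript, ENSMUST00000038863, was 2.12 times higher in the proline IP than in the control IP (2.105 to 2.135) and 2.46 times higher in the proline input than in the control input (2.35 to 2.58). In all 360 transcripts (2.96%) were at least 2-fold higher in the proline IP and 761 (6.25%) at least 2-fold lower, 206 and 413 of them beyond counting error. Of the 12169 unchanged transcripts in the simulated libraries, 211 were called higher and 255 lower, 103 of them beyond counting error. The median log2 difference was -0.15. The share of higher among called transcripts was 32.1% as deposited, 28.0% with equal FPKM totals and 48.1% with centred differences. The first differences under the naming rule rested on a single read in one of the libraries. A transcript of 703 nt went from 1 read in the control IP to 11 in the proline IP (ratio 20.6, 2.99 to 886), and one of 391 nt from 1 to 6 (ratio 11.2, 1.36 to 517). Among the falls, a transcript of 867 nt went from 22 reads to 1 (ratio 0.0851, 0.00206 to 0.526), and one of 962 nt from 20 to 1 (ratio 0.0936, 0.00226 to 0.585). Restricted to the 6591 transcripts with at least 60 reads in the IPs together, a limit chosen after seeing the data, 30 were higher and 110 lower.

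The IP followed the input weakly. The change between the IPs had a slope of 0.25 on the change between the inputs over 12168 transcripts, with a Pearson correlation of 0.29. Among the 2448 transcripts with at least 200 IP reads the slope was 0.27 and the correlation 0.56. The 1104 transcripts higher in the proline input had a median log2 difference of 1.47 there and 0.23 in the IP, and 117 of them (10.6%) were also at least 2-fold higher in the IP. The 388 lower ones had medians of -1.21 in the input and -0.53 in the IP, and 54 (13.9%) were at least 2-fold lower in the IP. These sets were picked on their input change, a choice that by itself favours a smaller change in the IP. Over all 12168 transcripts the IPs of control and proline had a Pearson correlation of 0.933 (SD of the log2 difference across transcripts 0.603) and the inputs 0.925 (SD 0.720). For the 2448 transcripts, which are selected on IP reads, the values were 0.978 (SD 0.325) for the IPs and 0.924 (SD 0.681) for the inputs.

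**Figure D3:**
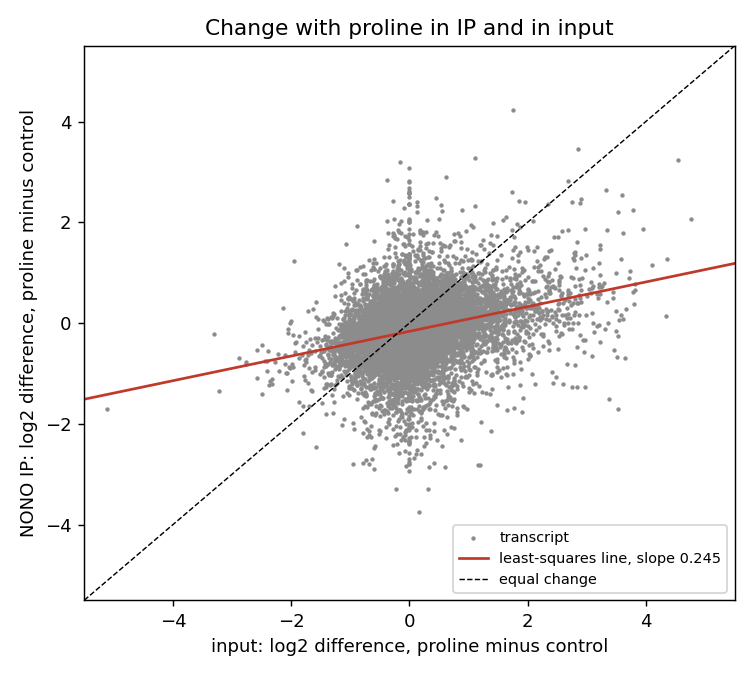
Change with proline in the NONO IP (vertical) against the change in the input (horizontal), each as a log2(FPKM + 1) difference of proline minus control, with 1 point per transcript for 12168 transcripts. The red least-squares line has a slope of 0.245 and lies far from the dashed line of equal change.

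The change in NONO enrichment, the main question of the design, combines all 4 libraries. Enrichment rose at least 2-fold with proline for 508 transcripts (4.18%) and fell at least 2-fold for 1677 (13.8%), with 370 and 1201 beyond counting error. Of the 12169 unchanged transcripts in the simulated libraries, 244 were called higher and 265 lower, 116 of them beyond counting error. The median log2 change was -0.16. For the 1215-nt transcript with the largest fall in the input, the enrichment was 12.2 times higher in proline (3.77 to 57.2), with an input that fell from 89.99 to 1.62 FPKM and an IP that went from 7.83 to 1.72 FPKM. For a transcript of 1150 nt it was 13.05 times higher (4.55 to 35.3), with an input of 16.7 FPKM in control and 3.59 in proline and IP values of 2.92 and 8.20 FPKM on 6 and 9 reads. The first falls under the naming rule, ranked on the log2(FPKM + 1) scale, were a ratio of 0.0276 for a transcript of 1793 nt (0.00784 to 0.135), whose input rose from 2.56 to 43.5 FPKM, and of 0.0291 for one of 2199 nt (0.0105 to 0.105), whose input rose from 2.91 to 29.5 FPKM. The most-read transcript, ENSMUST00000038863, had an enrichment ratio of 0.860 (0.821 to 0.901), and the 21388-nt transcript fell to a ratio of 0.569 (0.553 to 0.584).

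For the falls in enrichment the input moved more than the IP. Of the 1677 transcripts with lower enrichment in proline, 781 (46.6%) were at least 2-fold higher in the proline input, 514 (30.7%) were at least 2-fold lower in the proline IP, 42 were both and 424 neither. Their median log2 difference was 0.91 in the input and -0.54 in the IP. Of the 508 with higher enrichment, 132 (26.0%) were at least 2-fold lower in the input, 176 (34.6%) at least 2-fold higher in the IP, 4 both and 204 neither. Their median log2 difference was -0.57 in the input and 0.74 in the IP. With at least 60 IP reads, 71 of the 120 rises were at least 2-fold lower in the input and 2 at least 2-fold higher in the IP, with medians of -1.11 and 0.076. At that limit 310 of the 515 falls were at least 2-fold higher in the input and 42 at least 2-fold lower in the IP, with medians of 1.19 and -0.17. Lower calls outnumbered higher ones under every alternative run, with higher ones making up between 18.6% of the called transcripts with a pseudocount of 5 and 34.0% without the most-read transcript in the totals.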

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

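All tests in this part were chosen after the results had been seen. The enrichment of some transcripts went in opposite directions in control and in proline: 48 were at least 2-fold higher in the control IP and at least 2-fold lower in the proline IP, each against its own input, and 5 were the other way round. One of the 5 is the 1150-nt transcript described above, whose log2 enrichment was -2.17 in control and 1.002 in proline, a change of 3.18. These differences were not tested, since each side is 1 pair of libraries.

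Among the 4446 transcripts listed at 0 in both inputs, of which 175 reach a mean FPKM of 1 and enter the counts above, 71.0% had reads in the control IP and 46.3% in the proline IP. The median IP level was 0.520 FPKM in control and 0 in proline for these. It was higher, and nearly level, over the next classes: 0.602, 0.597 and 0.612 FPKM in control, and 0.372, 0.362 and 0.364 FPKM in proline, for transcripts above 0 and up to 0.01, from 0.01 to 0.03 and from 0.03 to 0.1 FPKM in the inputs. A candidate explanation is a background of uniform density in the IPs: for 1504 transcripts of at least 2000 nt with no input reads and at least 1 IP read, without which the length is not known, 88.4% of control IP read numbers lay inside the central 95% Poisson range of the common density, just short of the bound of 90% set for it, but for the 232 of at least 5000 nt only 79.3% did (exact 95% interval 73.5% to 84.3%), an interval that spans the bound of 80% set against it. If reads are independent, as the Poisson range takes them, a uniform background alone does not account for these reads. Of the 1504, 10.2% (8.75% to 11.9%) lay above the range, where 1.62% would under 1 density given at least 1 read. PCR copies, or reads of a pair counted apart, would break that independence and could raise this share, so a uniform background is not excluded. Selective recovery of RNAs scarce in the lysate would place the same transcripts above the range in both IPs; 27 were, 2.64 times the 10.2 that independent lists give, which lies between the bounds set for and against it, and reads from repeated or unlisted neighbouring sequence would do the same and were not tested.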

How the results depend on the processing

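The 11 counts (higher and lower in 5 comparisons, and the overlap of enriched transcripts) were recomputed under 6 planned and 4 added alternatives; the added ones (totals without the most-read transcript, the control IP thinned, the IP floor subtracted, at least 60 IP reads) were chosen after seeing the data. Of 110 values, 65 lay within 1.5 times the reported count. The 20 named differences, picked as largest, could hardly change sign. Of 184 values, 17 moved beyond counting error, 10 with a pseudocount of 5. The slope of IP change on input change stayed between 0.23 and 0.27, and the correlation of enrichment between 0.65 and 0.81. Restriction to protein-coding genes and the gene lists were not run, since transcripts have no names here, and leaving out replicates does not apply. Stricter filters lower counts by construction, as fewer transcripts enter, and so does a larger pseudocount, which shrinks low values; for the other settings the cause was not tested.

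With a pseudocount of 0.1, 640 transcripts were lower in the proline input, 580 higher and 1252 lower in the proline IP against the control IP, and enrichment rose for 766. With a pseudocount of 5 the counts higher and lower were 565 and 940 for control IP over input, 332 and 1218 for proline IP over input, 550 and 176 between inputs, 71 and 85 between IPs, and 133 and 580 for the change in enrichment, and the overlap was 259. Without a filter, 3507 were enriched in control and 2196 in proline, 733 were higher and 1839 lower between IPs, and enrichment rose for 885 and fell for 2856. At a mean FPKM of at least 5, 727 were enriched in control and 439 in proline with an overlap of 325, 150 were higher and 261 lower between IPs, and enrichment rose for 255 and fell for 845. With centred differences 904 were depleted in control, 1902 enriched and 1159 depleted in proline, and the overlap was 1269. Without the most-read transcript in the totals, 1636 were enriched in proline and 560 higher between IPs. With at least 60 IP reads, the counts higher and lower were 709 and 940 in control, 441 and 1046 in proline, 455 and 254 between inputs, 30 and 110 between IPs and 120 and 515 for the change in enrichment, with an overlap of 359.

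The median log2 difference moved by over 0.1 in control IP over input, from -0.14 to 0.20 without a filter, 0.027 with equal FPKM totals, 0.16 with centred differences, -0.012 without the most-read transcript, -0.30 at a mean FPKM of at least 5 and -0.27 with the IP floor subtracted. In proline IP over input it moved from -0.31 to 0 without a filter, -0.17 with equal totals, 0.092 centred, -0.052 without the most-read transcript and -0.20 with a pseudocount of 5. Between IPs it moved from -0.15 to -0.015 centred and -0.012 without that transcript, and for the change in enrichment from -0.16 to -0.059 and -0.029. Centring, which sets a median over abundant transcripts to 0, also turned that of the inputs to 0.042. The share of higher among called transcripts moved by over 10 percentage points in control IP over input from 48.0% to 61.5% with equal totals, 72.3% centred, 58.0% without the most-read transcript, 66.1% without a filter, 37.5% with a pseudocount of 5, 32.6% at a mean FPKM of at least 5 and 36.4% with the IP floor subtracted. In proline IP over input it moved from 31.3% to 62.1% centred, 50.2% without that transcript, 47.1% without a filter and 19.8% at a mean FPKM of at least 5. Between IPs it moved from 32.1% to 48.1% centred, 46.1% without that transcript, 45.5% with a pseudocount of 5, 44.9% with the floor subtracted and 21.4% with at least 60 IP reads, and for the change in enrichment from 23.3% to 34.0% without that transcript. A transcript of 3000 nt at 1 FPKM has 2.86 reads in the proline IP, which limits what low transcripts show. Thinning the control IP to that depth cannot test this, but kept counts using that IP within 1.5 times those reported.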

Other observations

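The tests in this part were chosen after the results had been seen. More transcripts were lower than higher in the proline IP against the control IP (761 and 360), and the median transcript was lower (-0.15 on the log2 scale); a candidate explanation is that ENSMUST00000038863 takes a larger share of the proline IP reads, 17.4% against 8.19%, which lowers the FPKM of all others. With that transcript left out of the totals the median was -0.012 and lower calls were 1.17 times the higher ones. Leaving it out rescales all other values of a library by a common factor, which those shares fix. Centring, which also shifts all transcripts alike, gave a median of -0.015 with 506 higher and 547 lower. The test thus cannot tell this transcript from another difference in scaling between the IPs. A uniform background of different level in the 2 IPs stays a candidate too. With the floor of each IP subtracted lower calls were 1.23 times the higher ones, with a median of -0.098. Each floor is a median that counts values of 0, which were more frequent in the shallower proline IP. The floors can thus differ through depth as well, so this test cannot tell background level from depth. The lower depth of the proline IP is argued against, since with the control IP thinned to the same depth, lower calls were still 1.80 times the higher ones, and 1.70 to 2.05 times over 100 random thinnings. For the change in enrichment falls remained 1.94 times the rises without the large transcript, though its median went from -0.16 to -0.029, so it is not enough alone. The larger imbalance under the same totals lies in the inputs, with 1106 transcripts higher and 389 lower in proline against 560 and 656 between IPs, and whether proline or the single cultures made it is open.

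The change between the IPs had a slope of 0.25 on the change between the inputs. Such a slope is not a ratio of the sizes of the changes. It combines their correlation (0.29) with their spreads across transcripts (SD 0.603 for the IPs and 0.720 for the inputs). Counting noise in the IP would lower the correlation but is unlikely to set the slope, in which the IP change is the fitted variable. The slope was 0.267 (0.248 to 0.288 over 1000 bootstrap samples of transcripts) among transcripts with at least 200 IP reads. Because noise in the fitted variable does not flatten such a slope, that limit tests it little. Counting noise in the inputs could flatten the slope, but it was 0.304 (0.285 to 0.324) with at least 1000 reads in each input. A uniform background in the IPs would also flatten it, but after subtraction of the floor it was 0.283 (0.261 to 0.303) for transcripts with a mean IP FPKM of at least 20. These intervals resample transcripts, which are not independent replicates, and leave out variation between libraries and cultures. What sets the slope is open: proline and the single cultures and preparations cannot be separated with 1 library per group, and no biological explanation was tested.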
